A study of Mus musculus with 2 samples.

How the data were processed

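Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map trimethylation of histone H3 at lysine 4 (H3K4me3), a histone mark found mainly at active and poised promoters. The chromatin came from sorted neurons of the mouse small intestine that carry NOS1, the neuronal nitric oxide synthase. The series held 2 libraries, 1 H3K4me3 immunoprecipitate and 1 input chromatin library, so there was 1 library of each kind and no replicate. One processed file was used, the peak list of the immunoprecipitate. No file of the input library was used here.

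The authors' deposited peak list gave each peak a position and a score. BWA, Picard and MACS2 and the genome build mm10 were named in the submitters' processing notes, without roles, order or versions. Per the file headers, the peaks came from MACS2 and the library was paired-end. The name of the deposited list names the input library as the control, which no other source used here states. The threshold, the treatment of duplicate reads and the scale of the score are not given in the sources used here. The smallest score was 2.0015. The score in the deposited list was therefore used only to rank, filter and describe peaks within this list. No read counts were part of the file, so the depth of either library is unknown and no depth-based interval was computed. Peak calling splits and loses weak domains first when depth is low, so both the presence and the width of a peak depend on an unknown depth.

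Gene positions came from a table of RefSeq gene models on GRCm38.p6, whose chromosome coordinates are those of mm10. The coordinates were checked by moving all peaks. With the peaks in place 61.4% of protein-coding genes had a peak at an end, against 12.4% after a move of 20 kb and 11.2% after a move of 100 kb. The table gave the start and end of each gene model without strand, transcripts or sequence. Start sites could therefore not be placed. In place of the planned window around start sites, a window of 1 kb to each side of both ends of the gene model was used, and a gene was counted as having a peak when at least 1 bp of a peak lay in either window. This also counts a peak at the 3′ end of a gene, including one that belongs to a neighbouring gene, and it misses start sites inside the model. The analysis covered 21887 protein-coding genes on the 21 chromosomes of the list.

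Before the data were examined, 23 gene lists were fixed: 20 lists of named markers with 381 symbols, all Hox genes, all olfactory receptor genes and all vomeronasal receptor genes. All symbols were found, 1 of them (Drgx) under the name Prrxl1. Only 2 genes, Etv1 and Gfra1, stood in more than 1 list. For each list the share of genes with a peak, the median width of the widest peak per gene and the median of the highest score per gene were computed. Each was set against 10000 random lists of the same size, drawn from all protein-coding genes for the share and from genes with a peak for width and score. A list was called above or below the random lists at a percentile of at least 98 or at most 2, with ties at mid-rank, and width and score were called only for lists with at least 5 genes with a peak. Among 23 lists, 0.92 would fall outside these limits by chance. The plan was to match the random lists on promoter CpG content, because CpG-rich promoters carry H3K4me3 in most cell types. No genome sequence was used here, so this matching was not done, and a list's percentile can follow the CpG content of its promoters. The percentiles describe this library and are not p-values, since genes are not replicates. Intervals of shares are exact 95% Clopper-Pearson intervals over genes or peaks, and do not cover variation between animals, sorts or libraries.

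The genes named below were chosen by a rule fixed before the data were examined. It took the members of the pan-neuronal, enteric neuron regulator and nitrergic lists, members of other lists that went against the majority of their list, up to 4 examples per list in order of width, the 15 genes with the widest peaks, the 10 with the highest scores and the 5 widest peaks away from protein-coding gene ends. Genes named outside this rule are marked as such, and a few genes that the rule takes are counted in their lists but not reported here by name. The alternatives fixed at the same time were the 50% and the 25% of peaks with the highest scores, windows of 500 bp and 2500 bp, peaks that cover the end of the model, genes with no other gene's end within 2 kb, and peaks closer than 1 kb merged. Matching on gene length in 10 groups, peaks anywhere over the gene model (with 1 kb to each side) and peaks at least 300 bp wide were added after seeing the data.

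The code was tested on simulated data. All 200 genes given a simulated peak were found, 199 with the simulated width. Each simulated peak was centred on a gene end, so finding it checks only that the code runs correctly. Of 200 random lists without effect, 3.0% were called above or below in share and 2.5% in width. All 50 simulated lists of 20 genes with 18 carrying a peak were called above. As each held the same share, their calls could hardly differ and do not measure a rate of detection. Of 50 lists with 15 of 20 members from the wider peaks, 44% were called wider, so moderate differences in width are often missed. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.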

Results

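H3K4me3 was profiled in 1 library of sorted NOS1+ neurons from the mouse small intestine, beside 1 input chromatin library. NOS1 marks the nitrergic neurons of the gut wall, which relax smooth muscle by releasing nitric oxide. The series sets no conditions against each other. The comparisons are therefore between places in the genome and between groups of genes within 1 library, and none has a replicate check. The list held 29924 peaks, which covered 28.7 Mb. Peak width had a median of 690 bp (interquartile range 271 to 1432 bp) and reached from 153 to 8862 bp. Sequencing depth is unknown.

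Peaks were concentrated at the ends of protein-coding genes. Of the 29924 peaks, 16152 (54.0%, exact 95% interval 53.4 to 54.5%) lay within 1 kb of an end of a protein-coding gene model, and they held 72.1% of the covered length. A further 7.03% lay at the end of another annotated gene, such as a long noncoding RNA. Peaks inside protein-coding genes made up 27.7%, those inside other genes 2.31%, and those between genes 8.93%. Peaks at protein-coding gene ends had a median width of 1190 bp and a median score of 115.9, against 333 bp and 10.6 for all other peaks. In all, 13431 of 21887 protein-coding genes (61.4%, exact interval 60.7 to 62.0%) carried a peak at an end. The share of peaks at gene ends was 22.3% in the lowest 10% of the scores and 90.6% in the highest 10%. In the 25% of the list with the highest scores, other peaks were no longer narrower, with a median of 1661.5 bp against 1617 bp at gene ends.

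Nos1, the gene that defined the sort, had no peak at either end of its gene model (chromosome 5, 117866839 to 117958840, mm10). The model held 1 peak, of 183 bp with a score of 13.01. Between 20.2 and 24.6 kb before the model's lower coordinate lay 8 narrow peaks, 153 to 290 bp wide, with scores from 4.33 to 9.67. Another, of 188 bp with a score of 4.85, lay further out, at 117781544. Beyond the upper coordinate lay 2 stronger peaks within 100 kb, one of 2142 bp with a score of 205.8 starting at 117976297 and one of 2452 bp with a score of 57.6 starting at 118027243. Whether any of these belongs to a Nos1 start site cannot be read from the gene table, which gives no strand. The peaks outside the model were not matched to the ends of neighbouring genes, so they may belong to other genes. Of the 11 genes of the nitrergic list, 6 had a peak at an end (54.5%, exact interval 23.4 to 83.3%, percentile 32 of random lists), with a median width of 2258 bp (percentile 97.97, just under the limit of 98, and percentile 98.06, called wider, with windows of 500 bp). Etv1, a transcription factor of inhibitory motor neurons, had a peak of 4843 bp with a score of 146.8, and Gfra1, a receptor subunit for GDNF, one of 4657 bp with a score of 120.9. These 2 genes had the widest peaks of the 6 and also stand in the list of enteric neuron regulators. The median width of the nitrergic list without them was not computed. Ass1, an enzyme that regenerates arginine, the substrate of nitric oxide synthase, had a peak of 2330 bp, and Nos1ap, an adaptor of NOS1, one of 2186 bp. Npy had a peak of 1358 bp with a score of 26.0 and Gal one of 501 bp with a score of 4.67, while Vip and Cartpt had none anywhere over the gene model. Adcyap1 held 1 peak of 192 bp inside its model, and Kcnab1 one of 2698 bp.

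**Figure D1:**
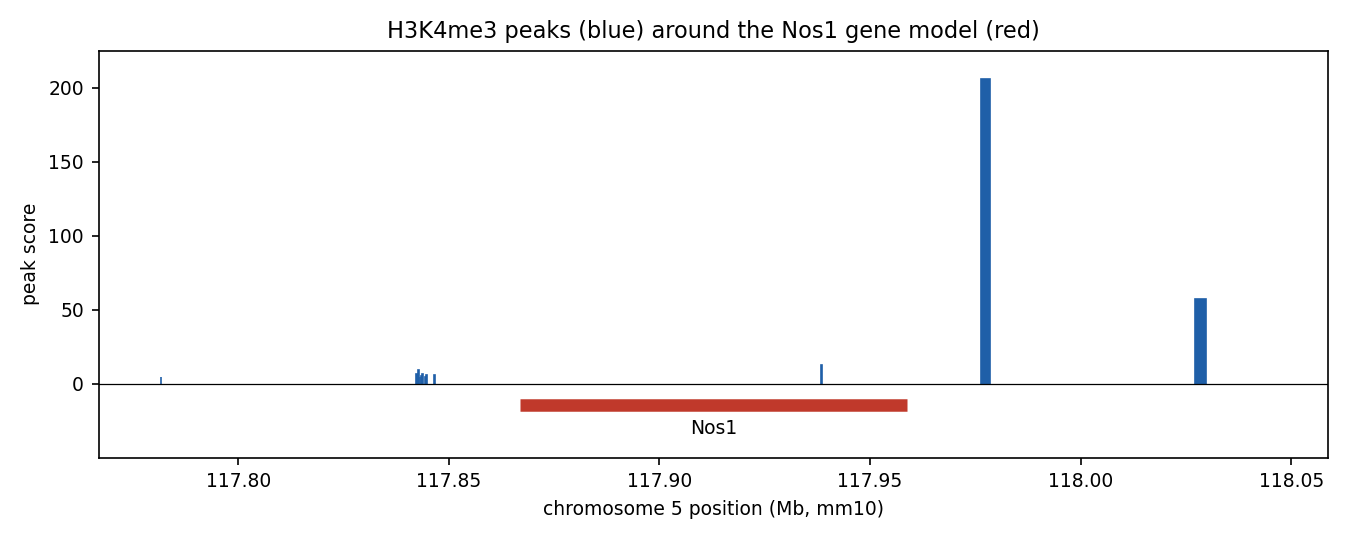
H3K4me3 peaks around Nos1 on chromosome 5 (position in Mb, mm10); each blue bar is a peak, as wide as the peak plus a thin outline that keeps narrow peaks visible, and as high as its score, and the red bar is the gene model. The gene holds 1 peak with a score of 13.01, 8 peaks with scores from 4.33 to 9.67 lie within 30 kb before its lower end with 1 more farther out, and 2 peaks with scores of 205.8 and 57.6 lie beyond its upper end. Neighbouring genes are not drawn, and peaks outside the model may belong to them.

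The regulators of enteric neuron identity had the greatest median width of the 18 lists whose width was compared. All 20 had a peak at an end (exact interval 83.2 to 100%, percentile 99.995), with a median width of 3442.5 bp (percentile 100) against 1496 bp for random lists. The transcription factor genes Meis1 (8526 bp), Hand2 (8107 bp), Tbx3 (7495 bp) and Meis2 (7438 bp) ranked 4, 5, 6 and 7 among all genes. The peak of Hand2 spanned chromosome 8 from 57316436 to 57324542. Gfra2, the receptor subunit for neurturin, had a peak of 5637 bp, and narrower ones lay at Sox4 (4220 bp), Klf7 (3605 bp), Tbx2 (3280 bp), Insm1 (2961 bp) and Sox11 (2761 bp). Ret, the receptor tyrosine kinase for GDNF family ligands, had a peak of 1340 bp with a score of 59.2, Phox2a one of 1388 bp, Tlx2 one of 1903 bp and Isl1 one of only 405 bp. The median score of the 20 was 100.5 (percentile 2.75, against 152.7 for random lists), called lower than random lists in both better-scored sets, with peaks that cover the end of the model and with peaks at least 300 bp wide. The call of greater width held under each of the 10 alternatives, and that of a higher share ended only in the 25% of the list with the highest scores. There 25% of the 20 genes kept a peak, the smallest number that allowed a width to be called. Single widths moved: Klf7 had 861 bp with windows of 500 bp or peaks that cover the end of the model, and Phox2a 921 bp in the 50% with the higher scores. With peaks closer than 1 kb merged, widths grew by over 1.5 times at Hand2 (23647 bp), Meis2 (16670 bp), Zeb2 (15755 bp, from 2655 bp), Tbx3 (15102 bp), Tbx2 (7148 bp), Ret (3439 bp), Phox2a (2285 bp) and Isl1 (829 bp).

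Most genes of general neuronal structure carried peaks, but narrow and low-scored ones. Low scores were common among the fixed lists: 13 of the 18 compared had a median score called below random lists and 0 above. Of the 20 pan-neuronal genes, 18 had a peak at an end (90%, exact interval 68.3 to 98.8%, percentile 99.71). Their median width was 968 bp (percentile 0.195, against 1497 bp for random lists) and their median score 19.5, below all 10000 random lists. Map2 (1731 bp, score 102.3), Elavl4 (982 bp, 96.9), which encodes the RNA-binding protein HuD, and Uchl1 (1879 bp, 60.5) stood highest. Tubb3 had a score of 36.9 (its peak also lies at an end of Mc1r), Gap43 47.5, Elavl3 25.5, Syn1 38.8 and Syt1 19.2. Snap25 (379 bp, score 11.6), Nefl (391 bp, 8.38), Prph (172 bp, 7.33, with a peak of 1405 bp inside its model) and Scg2 (232 bp, 3.33) stood near the bottom. Dcx had no peak over its model, and Rbfox3, which encodes NeuN, had none at an end but 3 inside. In the 25% of peaks with the highest scores the share was 0%, which turned the call from above to below random lists. This restates the low scores, since that 25% began at a score of 140.8 and the highest pan-neuronal score was 102.3. The call of a higher share also ended in the 50% with the higher scores, with peaks that cover the end of the model and with peaks at least 300 bp wide. The call of lesser width ended in that 50% and with peaks closer than 1 kb merged, where the median was 1511.5 bp (percentile 7.32) and Snap25 had 961 bp, Nefl 1050 bp and Tubb3 2177 bp; Snap25 (242 bp) and Nefl (239 bp) were narrower with windows of 500 bp, and Elavl4 had 1858 bp anywhere over its model.

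Genes of the synapse and of excitability, like most of the fixed lists, had low-scored peaks compared with random lists. All 22 synaptic vesicle genes had a peak (percentile 100), with a median of 1348.5 bp, among them Vamp2 (2514 bp, score 277.9), Rims2 (2419 bp) and Bsn (2141 bp, a peak outside its model that also lies at an end of Apeh). Of 27 voltage-gated channel genes 20 had a peak at an end (74.1%, percentile 90.8), led by Kcna1 (5482 bp), Kcnn3 (2867 bp), Kcnq5 (2848 bp) and Kcnd3 (2752 bp). Scn2a, Scn3a, Cacna1c, Cacna1d, Cacna1h and Kcna2 had peaks only inside their models, and Scn11a had none. Over the whole model 26 of the 27 channel genes carried a peak (percentile 99.995). Of 39 neurotransmitter receptor genes 29 had a peak at an end (74.4%, percentile 95.5), at a median width of 921 bp, below all 10000 random lists. Gria3 (2701 bp), the purinergic receptor gene P2ry1 (2571 bp), the muscarinic receptor gene Chrm2 (2511 bp) and Gria4 (2233 bp) were the widest. The serotonin receptor genes Htr3a and Htr3b, the dopamine receptor gene Drd2 and the ghrelin receptor gene Ghsr had no peak. The median scores of synaptic (89.7), channel (54.0) and receptor genes (22.2) lay below the random lists, at percentiles 0.90, 0.05 and 0. The synaptic share was no longer called above in the 25% of peaks with the highest scores and with peaks that cover the end of the model, and the receptor list was no longer called narrower in the 50% with the higher scores. The call of lower score for the synaptic list ended in the 25% with the highest scores (205.8, percentile 84.96), with windows of 500 bp or 2500 bp, with peaks that cover the end of the model and with peaks at least 300 bp wide. The receptor share fell below random lists in the 50% with the higher scores (28.2%, percentile 0.105) and in the 25% with the highest (2.56%, percentile 0), and the channel share in that 25% (3.70%, percentile 0.005), while the channel share was above random lists among genes with no other gene's end within 2 kb (76.2%, percentile 98.9).

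Markers of enteric neuron classes other than the nitrergic one mostly had no called peak at an end. Only 6 of 25 had a peak at an end (24.0%, exact interval 9.36 to 45.1%, percentile 0.02). These were Bnc2 (2704 bp), Nog (1482 bp), Slc6a4 (842 bp), Calca (651 bp), Slc5a7 (577 bp) and Penk (570 bp). Over the gene model 9 of the 25 had a peak (36.0%, percentile 0.08), with Ntng1 (2372 bp), Gad1 (489 bp) and Gad2 (522 bp) added, which are named after their values were seen. Markers of sensory and sympathetic neurons were also below random lists, with 5 of 18 carrying a peak (27.8%, percentile 0.24): Hand1, Neurog2, Pou4f1, Neurog1 and Gata2. That call ended among genes with no other gene's end within 2 kb and with peaks anywhere over the model. Of 22 regulators of the central nervous system 11 had a peak (50%, percentile 13.8), a share that was below random lists in the 50% of peaks with the higher scores (22.7%, percentile 0.19) and in the 25% with the highest (4.55%, percentile 0.11). Dlx1 (3484 bp), Dlx2 (3087 bp), Lmx1b (2706 bp) and Pitx3 (1898 bp, a peak it shares with Elovl3) were the widest. The median width of this list was called greater in that 50% (2706 bp) and lesser with windows of 2500 bp and over the whole model (950 bp).

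**Figure D2:**
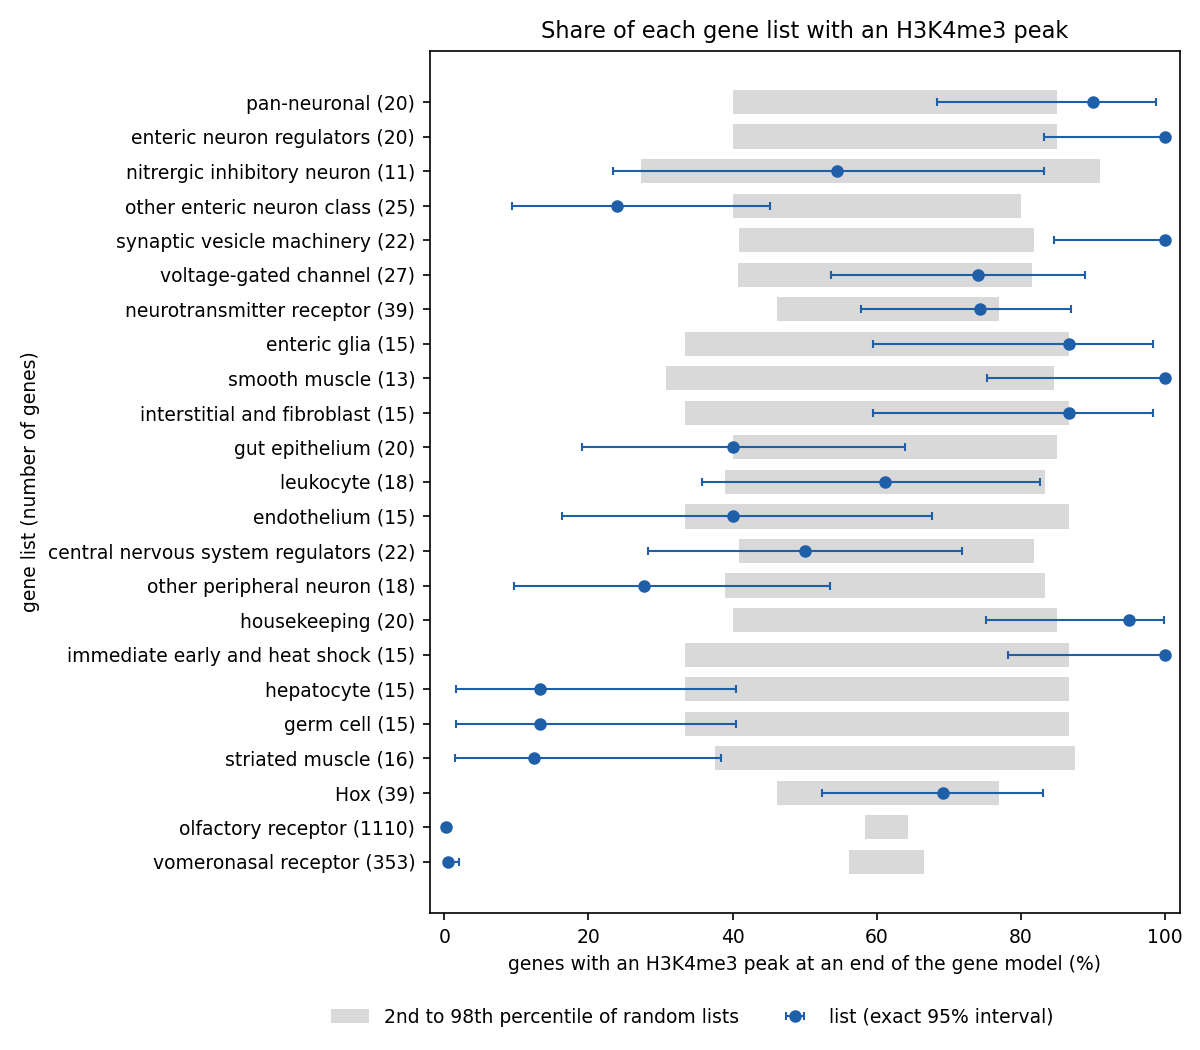
Share of the genes of each list with an H3K4me3 peak at an end of the gene model (percent, points with exact 95% intervals), beside the range from percentile 2 to percentile 98 of 10000 random lists of the same size (grey bars); the number of genes stands after each name. Of the lists, 6 lie above the grey range by the mid-rank percentile and 7 below it.

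Markers of glia, smooth muscle and interstitial cells also carried peaks. Of 15 enteric glial genes 13 had a peak at an end (86.7%, exact interval 59.5 to 98.3%, percentile 97.985, just under the limit of 98), and all 15 had one over the gene model (percentile 99.865). The share at an end was called above random lists with windows of 500 bp (percentile 98.6) and with peaks at least 300 bp wide (percentile 98.56). Their median width was 2049 bp (percentile 98.4) and their median score 85.9 (percentile 3.11), called lower in the 50% of peaks with the higher scores (percentile 1.19) and with peaks at least 300 bp wide (percentile 1.99). Sox10, the transcription factor of neural crest and glia, had a peak of 6775 bp, rank 13 among all genes, on chromosome 15 from 79157709 to 79164483. Foxd3 (5004 bp), Sox2 (4588 bp) and Gpr37l1 (3214 bp) followed, while Col28a1 had a peak only inside its model. The call of greater width for this list ended with windows of 500 bp or 2500 bp, with peaks that cover the end of the model and with peaks at least 300 bp wide. All 13 smooth muscle genes had a peak (percentile 99.9), with a median of 921 bp (percentile 0.37) and a median score of 31.5. Tpm2 (3992 bp), Myl9 (2129 bp), Smtn (1576 bp) and Tagln (1503 bp) were the widest. With peaks closer than 1 kb merged, the median width of the smooth muscle list was 3398 bp (percentile 100), with a median of 4 peaks per merged region against 1 for all genes with a peak. The higher share of this list ended in the 50% of peaks with the higher scores and with peaks that cover the end of the model, and in the 25% with the highest scores it turned to below, at 7.69%. The call of lesser width ended in that 50% and with peaks that cover the end. The interstitial and fibroblast list had 13 of 15 (percentile 97.7; above random lists with windows of 2500 bp, among genes with no other gene's end within 2 kb and over the whole model, and below them, at 6.67%, in the 25% with the highest scores), with Vim (4109 bp), Col6a1 (2041 bp), Col1a1 (1877 bp) and Col3a1 (1848 bp) in front and Pdgfra and Ano1 marked only inside.

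Where epithelial, endothelial and leukocyte markers carried peaks, these were narrow and, as in most of the fixed lists, low-scored, while the shares of genes with a peak stayed inside the limits of random lists. Of 20 epithelial genes 8 had a peak (40.0%, percentile 2.79), with a median width of 553.5 bp (percentile 0.02) and a median score of 19.5 (percentile 0.01): Lgr5, Krt8, Epcam, Krt19, Krt18, Cdh1, Cldn7 and Elf3. Of 15 endothelial genes 6 had one (40.0%, percentile 4.88), with a median width of 883.5 bp (percentile 1.99) and a median score of 15.8 (percentile 0.08), at Prox1, Kdr, Flt1, Esam, Cldn5 and Erg. Of 18 leukocyte genes 11 had one (61.1%, percentile 48.3), with a median width of 375 bp (percentile 0.01) and a median score of 9.48, below all 10000 random lists. The leukocyte genes with the highest scores, Cd79a (164.5) and Cd68 (149.8), share their peaks with an end of Arhgef1 and of Mpdu1. Ptprc, Cd3e, Itgam, Itgb2, Adgre1 and Cx3cr1 had none at an end. With peaks closer than 1 kb merged the leukocyte and endothelial lists were no longer called narrower, and the endothelial call also ended with windows of 500 bp or 2500 bp, among genes with no other gene's end within 2 kb, with matching on gene length and over the whole model. The epithelial share was called below random lists with windows of 500 bp or 2500 bp, with peaks that cover the end, with peaks at least 300 bp wide, in both better-scored sets and with matching on gene length, the leukocyte share in all of these but the larger window and the matching, and the endothelial share with peaks that cover the end, in both better-scored sets and with the matching.

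**Figure D3:**
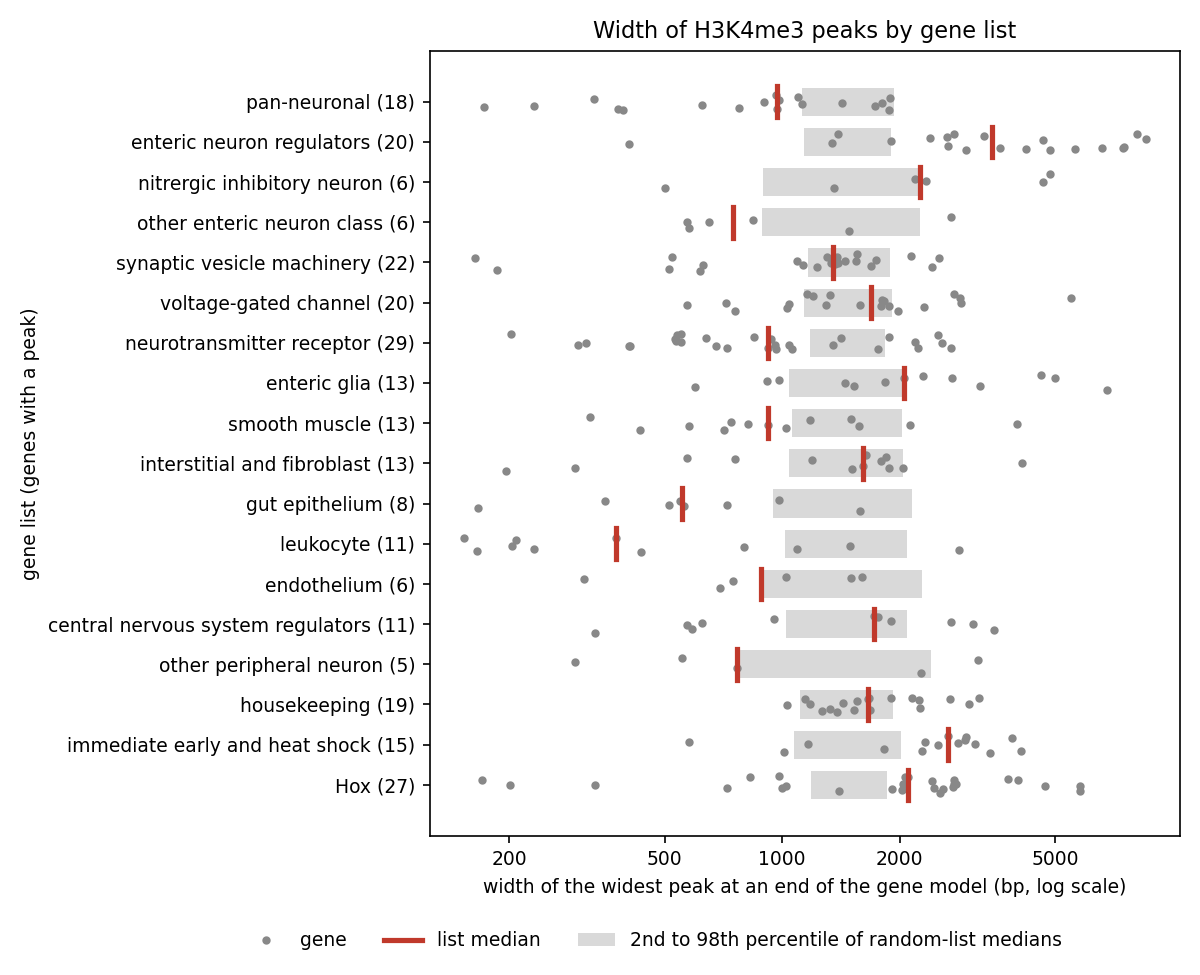
Width of the widest H3K4me3 peak at an end of the gene model (bp, log scale) for each gene with a peak (grey points), the median of each list (red line) and the range from percentile 2 to percentile 98 of the medians of 10000 random lists (grey bars), for the 18 lists with at least 5 such genes. The enteric neuron regulators reach a median of 3442.5 bp and the pan-neuronal genes 968 bp.

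The Hox clusters, whose genes mark position along the body axis, were divided by paralog number. Of the 23 genes of paralog groups 1 to 8, 22 had a peak at an end (95.7%, exact interval 78.1 to 99.9%), with a median width of 2491 bp and scores from 17.9 to 217.9. Hoxb1 was the exception. Of the 16 genes of groups 9 to 13, 5 had a peak (31.2%, exact interval 11.0 to 58.7%), none with a score above 11.8. The size of the split depended on the setting, while groups 1 to 8 had the higher share in each setting computed. With 2500 bp in place of 1 kb, 6 of the 16 had a peak, and the added one, 1078 bp before the lower end of the Hoxa9 model (chromosome 6, 52221228 to 52222019), had a score of 103.5. In the 50% of peaks with the higher scores the shares were 82.6% for groups 1 to 8 and 0% for groups 9 to 13. In the 25% with the highest scores they were 34.8% (exact interval 16.4 to 57.3%) and 0% (0 to 20.6%), with overlapping intervals. Both values of 0% restate the low scores of groups 9 to 13, since that 50% began at a score of 35.7. With peaks that cover the end of the model the shares were 78.3% and 18.8%, and with peaks at least 300 bp wide 95.7% and 18.8%. Among genes with no other gene's end within 2 kb they were 92.9% (exact interval 66.1 to 99.8%) and 41.7% (15.2 to 72.3%), with overlapping intervals. The highest score was at Hoxa5 and Hoxa6, which share a peak (217.9). Hoxb7 and Hoxb8 shared the widest peak, of 5775 bp. The division at paralog group 8 was chosen after the values were seen, and all 39 Hox genes together had a share of 69.2% (percentile 84.2). The median width of the 27 with a peak was 2104 bp (percentile 99.87), called wider. That call ended among genes with no other gene's end within 2 kb (percentile 91.7). Their median score was 76.0 (percentile 0.12), called lower except in the 25% of peaks with the highest scores (percentile 37.5).

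**Figure D4:**
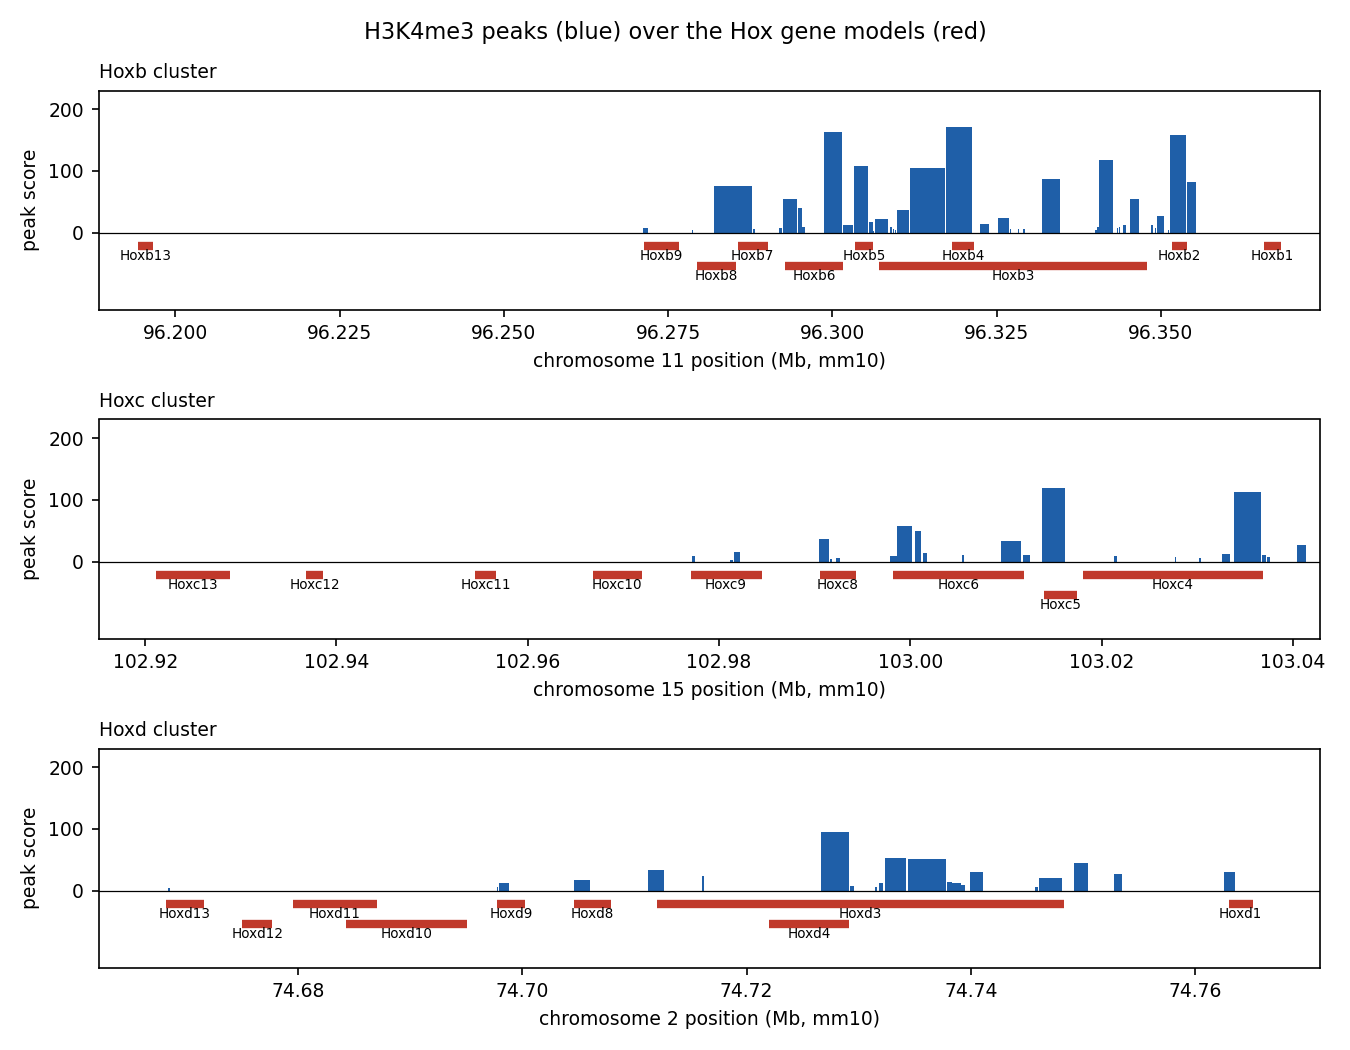
H3K4me3 peaks (blue, as wide as the peak and as high as its score) over the gene models (red) of the Hoxb, Hoxc and Hoxd clusters, with the position in Mb (mm10) on the x axes. Within 1 kb of the ends of the genes of groups 9 to 13 drawn here no peak has a score above 11.8. The Hoxa cluster is not drawn, and it holds a peak with a score of 103.5 at 1078 bp before the lower end of the Hoxa9 model.

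Reference lists gave the range of the assay. Of 20 housekeeping genes 19 had a peak at an end (95%, percentile 99.97), with a median width of 1661 bp and a median score of 187.3; Hsp90ab1 (3200 bp), Actb (3017 bp), Ppia (2689 bp) and Pgk1 (2247 bp) were the widest, and Ywhaz had its peak inside the model. All 15 immediate early and heat shock genes, which respond to activity and to cell stress, had a peak (percentile 99.98), with a median of 2651 bp (percentile 100). Atf3 (4084 bp), Egr1 (3866 bp), Fos (3398 bp) and Jun (3124 bp) were the widest of these. The higher share of both lists ended with peaks that cover the end of the model, and that of the immediate early and heat shock list also in the 25% of peaks with the highest scores. Genes of tissues that the sort should not hold were nearly free of peaks: 2 of 15 hepatocyte genes (Apoa2, whose peak also lies at Tomm40l, and Apoa1), 2 of 15 germ cell genes (Gdf9, whose peak also lies at Uqcrq, and Dazl) and 2 of 16 striated muscle genes (Ckm and Acta1) had one. Among olfactory receptor genes it was 2 of 1110 (0.18%, exact interval 0.0218 to 0.649%), Olfr1033 and Olfr94. Among vomeronasal receptor genes it was 2 of 353 (0.567%, exact interval 0.0687 to 2.03%), Vmn1r4, whose peak also lies at an end of Nt5c3, and Vmn2r29. These receptor families hold near-identical copies, at which reads that map to several places can be lost.

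Beyond the fixed lists, the widest peak at any protein-coding gene was that of Pcdh7, a protocadherin, with 8862 bp on chromosome 5 from 57714134 to 57722995. A peak of 8613 bp lay at the adjoining ends of Rhof and Setd1b, and one of 7376 bp at those of Tshz1 and Zadh2. Amotl2 (7223 bp), Fosl2 (7052 bp), Fgf9 (6787 bp), Arhgef17 (6690 bp) and Tgif1 (6676 bp) completed the 15 widest with the regulators and Sox10. The highest scores at gene ends belonged to other genes: Hjurp (572.0), Trim39 (342.9), Gm40469 (340.7), Blcap (315.1), Atg2b and Gskip (312.1), Cse1l and Nup35 (309.9), and Cdipt and Cdiptos (307.7). Peaks with high scores were not checked for mapping artefacts. Away from protein-coding gene ends, the widest peaks were one of 7839 bp at Malat1, a long noncoding RNA gene (chromosome 19, 5795783 to 5803621), and one of 6693 bp inside Zeb2, at an end of its antisense gene Zeb2os (chromosome 2, 45107253 to 45113945). Peaks inside Nr2f2 (6688 bp), Pdgfa (6049 bp) and Kcna2 (5701 bp) followed.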

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

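Of 10 alternatives, 7 were fixed before the data were examined and 3 (matching on gene length, peaks over the model, peaks at least 300 bp wide) were chosen after seeing the data; the 5′-most start site alone and matching on CpG content were not run, for want of strand and sequence. Of 632 values recomputed per list, 544 had the same call or again none, 42 lost a call, 43 gained one and 3 reversed. The 544 include widths and scores of lists with fewer than 5 genes with a peak in the main setting, which could not be called. Another 36 values could be called in the main setting but rested on fewer than 5 genes under the alternative, too few for a call. With the 50% and the 25% of the peaks with the highest scores the list held 14971 and 7481 peaks, of which 79.4% and 89.1% lay at gene ends; their median widths were 1452 and 1617 bp at gene ends and 1156 and 1661.5 bp elsewhere, and 53.1% and 34.5% of genes had a peak. Lists below random lists then numbered 12 and 16, lists above 4 and 1, and narrower lists 0 in both, among only 12 and 5 lists with enough genes in place of 18, sets that are filtered on the score itself. In the 25% set, 2 calls reversed from above to below: the pan-neuronal share was 0% and the smooth muscle share 7.69%. As both sets are filtered on the score, falls in the share of low-scored lists are no separate check of the share. With windows of 500 and 2500 bp, 48.7% and 65.4% of peaks lay at gene ends, with medians of 1265 and 1016 bp there, 356 bp elsewhere for the larger window, and 59.2% and 64.4% of genes with a peak. Peaks that cover the end of the model were 31.97% of all (medians 1529 bp, and 382 bp for the others), 47.6% of genes had one, lists above fell to 1, the enteric neuron regulators, and narrower lists to 2 (13 lists with enough genes). Among genes with no other gene's end within 2 kb 51.6% had a peak. Merging peaks closer than 1 kb gave 60.3% at gene ends, medians of 1726 and 569 bp, 3 narrower lists and one reversal, the smooth muscle width of 3398 bp. Peaks anywhere over the model were 84.5% (medians 827 and 351 bp; 67.0% of genes), and peaks at least 300 bp wide lay at gene ends in 65.0% (medians 1330 and 640 bp; 59.6% of genes). The greater width of the enteric neuron regulators and of the immediate early genes held in all 10. The 10 reuse the same peaks and are not separate checks, and matching on gene length changed only the random lists. Of 309 widths recomputed for single genes of the pan-neuronal, enteric neuron regulator and nitrergic lists, 265 were unchanged. The score-filtered sets also held fewer peaks, and the cause of the changes between settings was not tested. Depth is unknown, so a missing peak sets no upper limit on the mark.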

Other observations

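Apart from the merging of peaks closer than 1 kb, which was planned, all tests in this part were chosen after the results were seen. Groups of genes with a shared symbol stem were compared in width, for 78 stems with at least 15 genes with a peak. Sox genes were widest, with a median of 2761 bp over 15 genes (percentile 100), and Klf genes followed with 2657 bp over 15 genes (percentile 100). Zbtb (37 genes, 1917 bp), Phf (19 genes, 1943 bp) and Ppp genes (66 genes, 1766 bp) also lay above percentile 98. Zfp genes, mostly zinc finger proteins, were narrower, at 1362 bp over 330 genes (percentile 0.10), as were Slc transporter genes at 1369 bp over 243 genes (percentile 0.955) and Cfap genes, named for cilia and flagella, at 977 bp over 27 genes (percentile 0.03). In all 5 stems were wider and 3 narrower. With 78 stems some would fall outside the limits by chance, and stems near them, such as Phf (percentile 98.28), cannot be told from chance. The Sox and Klf stems also hold genes of the fixed lists, such as Sox10 and Klf7.

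On the Y chromosome 4 of 256 protein-coding genes had a peak: Ddx3y (score 49.6), Uty (44.9), Eif2s3y (52.8) and Kdm5d (34.0). Xist, the noncoding RNA gene of X inactivation, had 2 peaks at its ends, the wider of 469 bp, with a top score of 15.4. On the X chromosome 46.0% of protein-coding genes had a peak. The highest score of the whole list, 702.6, belonged to a peak of 733 bp on chromosome 2 (98666575 to 98667307), 1034903 bp from the nearest protein-coding gene. Scores of 511.8 and 415.0 belonged to peaks of 944 and 857 bp on chromosome 8, at 19784514 and 20122081, which also lie at no protein-coding gene end. The peak at Gm40469, at 20550060 on the same chromosome, was of like width (936 bp). Peaks were not filtered here for regions prone to mapping artefacts, and whether these peaks are such artefacts was not tested.

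Peaks over markers of other gut cells form the first pattern to follow up. The share of genes with a peak over the gene model was 100% for enteric glia, smooth muscle and the interstitial and fibroblast list, 45.0% for epithelium, 66.7% for leukocytes and 53.3% for endothelium, with median top scores of 84.5, 31.5, 44.9, 19.1, 9.40 and 32.1 in this order; none of these genes stood in another list. Cells of these types in the sorted fraction are a candidate source, though the sort for NOS1 should remove them, but the test cannot tell: its criterion, nearly all markers with a peak and a share above percentile 98, was not met by the nitrergic list of the sorted class itself (81.8%, percentile 83.8). A low share therefore does not show that a cell type was absent. This control does not tell whether a share near 100% can arise without the cells, so such a share does not settle that they were present. Among lists of tissues outside the gut, the share over the model was 13.3% for hepatocyte and for germ cell genes and 18.8% for striated muscle. It was 68.2% for regulators of the central nervous system. That neurons hold H3K4me3 at genes of related cells without transcribing them, and promoter CpG content, were not tested.

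The scores of neuronal and glial genes form the second pattern. The median top score was 85.9 for the glial list and 19.5 for the pan-neuronal list, a difference of 66.4 that lay at percentile 99.64 of shuffles of the genes between both lists. Glia outnumbering neurons in the sorted fraction is a candidate explanation, but the enteric neuron regulators had a median score of 100.5, itself at percentile 2.75 of random lists, and their difference from glia lay at percentile 33.3 of the shuffles. As regulators such as Hand2, Sox4 and Meis1 are also active outside neurons, the tables cannot settle the explanation. A biological difference, with structural genes of mature neurons carrying less H3K4me3 than regulators, remains open and untested.

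Low-scored peaks often lay beside others. Of the 10% of peaks with the lowest scores, 72.6% lay within 1 kb of another peak, against 56.0% of all peaks and 49.9% of the 10% with the highest scores. Merging all peaks closer than 1 kb, whatever their score, took the smooth muscle list from narrower than random lists to wider, at 3398 bp. Whether the merged peaks are parts of 1 domain or separate neighbours was not tested.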
